A study of Lactococcus cremoris with 8 samples.

How the data were processed

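RNA from 8 samples of Lactococcus cremoris NZ9000 was sequenced on an Ion Proton with a standard library kit, per the labels' protocols. Cells were lysed with glass beads and total RNA was isolated with phenol and chloroform, per the labels. Bowtie2 is named, with no version, in the submitters' processing notes. The counting program, the read filters and the use of strand are not given in the sources used here. The labels name the assembly ASM14320v1, while the files hold the MG1363 chromosome of 2529478 bases with added small RNA features.

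Each per-sample file holds a coverage column, an RPKM column and a normalized RPKM column, per the file headers. The first is headed as a count, but few features hold 1 to 9 (4 to 15 per library) while 61 to 190 hold 10 to 60, and the most common low values are 12 to 37. A single read thus adds about its length, and the deposited column was treated as summed base coverage, a signal and not a number of reads. Tests made for read counts were therefore not used, although the plan had named one for the case of read counts; limma, named there for other units, took its place. In the deposited files, RPKM equals coverage per base times 1 factor per library, within 0.0802% for features with high coverage. The authors' normalized RPKM is RPKM times a second factor, which sets the median over all rows of a file to 1000 to 1005. The authors' tables of the whole series equal these columns for every row they list. That table for the MAPS experiment has 2597 rows and no small RNAs, so the per-sample files were used. Second copies of tRNA and rRNA rows in the MAPS files were left out, which gave 2842 features: 2434 protein-coding genes, 82 pseudogenes, 63 tRNA, 18 rRNA and 245 small RNA features, all of them windows of 101 bases. Gene symbols, present for 1294 features, came from the deposited annotation. Of the 245 small RNA features, 135 have the same position under the same name there, and 108 have a position listed under another name.

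Groups were taken from the labels. log2(normalized RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with a mean trend and group as the only term, separately for the 4 libraries of each experiment, since these were scaled separately. Features with at least 5 normalized RPKM in at least 2 libraries were tested, with Benjamini-Hochberg adjustment and a false discovery rate of 0.05. All adjusted p-values of features come from limma. Fold changes are on the log2(value + 1) scale, which understates changes of low features. Of 33 gene lists fixed before the data were examined, those with at least 3 tested members, all but 1, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and fry were alternatives. Both rest on the 2 residual degrees of freedom of a comparison, so a list could hardly pass, and a call lost there is not evidence against a list. With an estimated correlation nearly all lists of a comparison share 1 adjusted p. For the lists that passed, the estimates lay above the preset, from 0.018 to 0.875. Where members vary together more than the preset assumes, its adjusted p-values are too small. The overlap was tested with Fisher's exact test in R, and tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

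The features named were fixed by a rule: CisR, and, since fewer than 5 features passed in each direction, the 8 with the smallest p in each direction. To these were added up to 4 members with the largest absolute log2 fold change of each list that passed and of the cold shock, small RNA and chaperone lists, and up to 10 shared features. Other features named, such as the 5S rRNA group, pflA and busR in their lists, and the calls of alternatives, were chosen after their values were seen.

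The procedure was tested on simulated data, in 20 simulations per comparison with 200 changed features each. In the overexpression comparison (2640 features), limma called 14.1% of features changed 2-fold, 52.3% of those changed 4-fold, 68.9% at 8-fold and 85.7% at 64-fold. In the MAPS comparison (2659 features) it called 1.32%, 26.6%, 53.2% and 75.2%. False calls were 4.04% and 4.20% of calls. The simulated features were independent and their spreads were drawn from limma's own fit, so a share near the threshold was built in. Real features varied together, with an estimated correlation of 0.875 in the tRNA list with overexpression. With 200 changed features the adjustment is also milder than where few change, so the percentages called may be too high. Small changes were therefore mostly out of reach, above all in the MAPS comparison, where rRNA took over 91% of the coverage.

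Alternatives tried were pseudocounts of 0.1 and 10, no filter, scaling to total base coverage with and without CisR, rRNA and tRNA, a replicate block, all 8 libraries in 1 fit, a false discovery rate of 0.1, a minimum absolute log2 fold change of 1, and leaving out each library. Added after seeing the data were median-of-ratios scaling, a minimum mean base coverage of 1000, the overexpression fit without tRNA and rRNA, a crossed pairing in the MAPS comparison, and the list tests under other scalings and filters.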

Results

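The series measured RNA in Lactococcus cremoris NZ9000, a laboratory strain derived from MG1363 that is used for nisin-induced expression. The series' title names CisR, listed as LLMGnc_082, as a small RNA induced by cold stress, and its aim was to find the targets of that RNA. Cultures grew at 30 °C in M17 broth with 0.5% glucose, were treated with nisin and were harvested in exponential growth. In the overexpression experiment, 2 libraries of cells with the empty vector pNZ8048 were set against 2 libraries of cells overexpressing CisR. In the second experiment, named MAPS in the series' design text, 2 libraries with MS2-tagged CisR were set against 2 libraries with untagged CisR. MAPS stands for MS2 affinity purification coupled with RNA sequencing, in which an RNA carrying the MS2 aptamer is held on a column together with its partners. The labels give total RNA for all 8 libraries and name no eluate. The replicate letters A and B name separate samples, but nothing says that they came from separate cultures, so every p-value below measures only the spread between these samples, which may be technical.

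Total base coverage over the 2842 features was 661 and 671 Mb (megabases) in the empty vector libraries, and 241 Mb in replicate A and 1238 Mb in replicate B of CisR overexpression. In the MAPS experiment it was 1791 and 1974 Mb in the untagged libraries and 1758 and 888 Mb in the MS2-tagged libraries. rRNA features took 1.09% to 1.93% of the coverage in the overexpression experiment and 91.2% to 95.7% in the MAPS experiment. The coverage outside rRNA was therefore 60.9 to 157 Mb in the MAPS libraries, against 237 to 1225 Mb in the overexpression libraries. The number of reads behind a value is unknown, so no counting interval can be given.

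CisR lies on the plus strand of the MG1363 chromosome at 1094292 to 1094392, between genes. The upstream neighbour on the same strand is llmg_1129, a cell wall surface anchor family protein gene that ends 65 bases before it, and the next gene, llmg_1130, begins 581 bases after it. The deposited annotation gives this position the name LLMGnc_083 and places LLMGnc_082 at 1088154 to 1088254 on the minus strand, a position that overlaps llmg_1125 and that the value files call LLMGnc_081. The value files' names were used here. At the other position the normalized RPKM was 836.5 and 1353.2 with the empty vector and 198.2 and 576.4 with CisR overexpression, so it was not the position whose level was raised in the overexpressing libraries.

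The first comparison asks what overexpression of CisR does to the transcriptome. CisR itself rose 52.0-fold: its normalized RPKM was 5372.9 and 5141.3 in the empty vector libraries and 226297.9 and 329771.5 in the overexpression libraries (log2 fold change 5.70, SE 0.22, n = 2 per group, limma adjusted p = 0.00268). No other feature passed the threshold. The largest coordinated difference was in tRNA features, of which 61 of 63 were lower with CisR overexpression and 60 lay below both empty vector libraries. Genes of ribosomal proteins, pyrimidine synthesis and glycolysis were also mostly lower, by smaller amounts that depended on how the libraries were scaled.

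**Figure D1:**
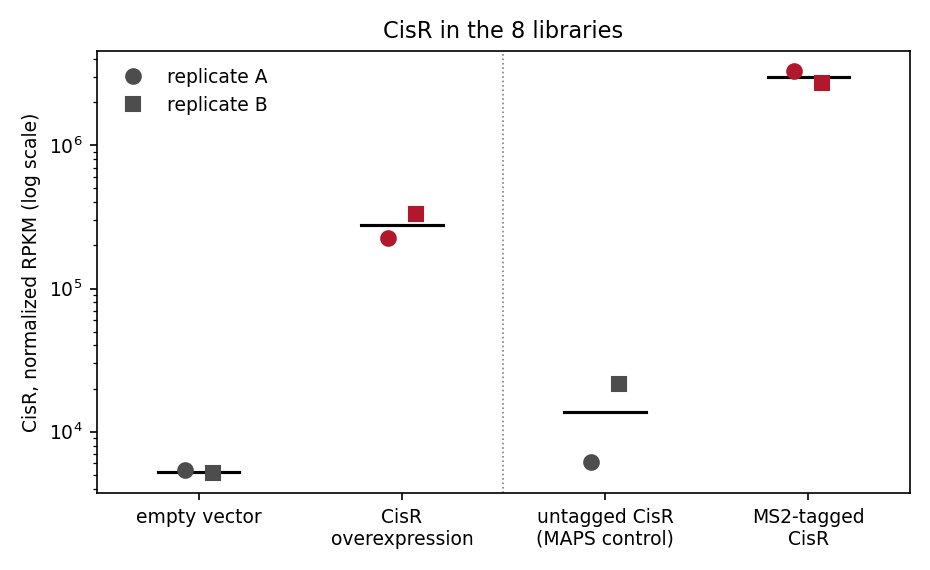
Normalized RPKM of CisR on a log scale in each of the 8 libraries, with circles for replicate A, squares for replicate B and a bar at each group mean. The values are 5372.9 and 5141.3 with the empty vector against 226297.9 and 329771.5 with overexpression, and 6181.4 and 21360.1 without the tag against 3312881.8 and 2728382.3 with it; the 2 experiments, parted by the dotted line, were scaled separately.

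Of the 2640 features tested with limma, 1 rose and 0 fell at a false discovery rate of 0.05. At an unadjusted p under 0.05 there were 409 features, 75 higher and 334 lower, where 132 would be reached by chance. That split rested on the scaling: with total base coverage scaling 1101 features reached it, 1020 higher and 81 lower. With CisR, rRNA and tRNA left out of that total there were 582, 450 higher and 132 lower, and with median-of-ratios scaling, chosen after seeing the data, 396, 159 higher and 237 lower. The groups did not overlap for 49.3% of features, where chance gives 33.3% for 2 against 2. The number past the false discovery rate of 0.05 depended on single libraries: against 1 with all 4, it was 64 without empty vector replicate A, 28 without replicate B, 150 without overexpression replicate A and 605 without replicate B. Across features, overexpression replicate B correlated more with empty vector replicate A (r = 0.958) than with overexpression replicate A (r = 0.931). Features are not independent replicates, and these values describe the libraries only.

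Among the features with the smallest p, none of which passed the threshold except CisR, pepN (llmg_0319) came first by p after CisR. It is the aminopeptidase gene into which the nisin sensor genes nisRK are integrated in NZ9000. It had 6293 and 7186.7 normalized RPKM with the empty vector and 20033.7 and 18303.5 with overexpression (log2 fold change 1.51, SE 0.16, adjusted p = 0.145). The small RNA LLMGnc_063 stood at 2058.6 and 1882.7 against 4841.6 and 5070.9 (1.33, adjusted p = 0.145), and LLMGnc_184 at 83.9 and 52.7 against 877.2 and 377 (3.09, adjusted p = 0.178). The others that were higher were llmg_0436 (1.72), LLMGnc_154 (0.79), fabZ, a dehydratase of fatty acid synthesis (0.77), and llmg_1259 (0.73). On the lower side stood the small RNA LLMGnc_064, with 460131.3 and 514448.8 against 82551.1 and 139782.9 (-2.18, SE 0.32, adjusted p = 0.145), cutC, annotated as a copper homeostasis gene (-1.30), llmg_1986 (-1.39), and the cobalt transporter gene cbiO at llmg_0288, with 9289 and 10142.3 against 4673.8 and 5012.6. The remaining 4 were tRNA features, llmg_tRNA_58 (-2.56), llmg_tRNA_47 (-2.52), llmg_tRNA_35 (-1.66) and llmg_tRNA_11 (-1.27). With total base coverage scaling, which moved the median of all features by 0.80, the values were 2.31 for pepN, -1.38 for LLMGnc_064, -0.50 for cutC, -0.59 for llmg_1986 and -0.20 for cbiO. How reads from identical tRNA copies were counted is not given, so single tRNA features are uncertain.

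The tRNA features had a median log2 fold change of -1.76 against -0.17 for all tested features. Of the 63, 51 fell when p was adjusted over the list alone and 0 over all features. Over all features, 19 and 6 tRNA features passed without empty vector replicates A and B, and 37 and 54 without overexpression replicates A and B. The set test with a preset correlation gave an adjusted p = 3.1e-24. The preset of 0.01 lies far below the 0.875 estimated for this list, so this adjusted p is too small. With an estimated correlation the adjusted p was 0.947, a value that nearly all lists share there. The features with the largest differences were llmg_tRNA_40 (-3.68), at only 35.7 and 136.3 normalized RPKM with overexpression, llmg_tRNA_53 (-2.87), llmg_tRNA_41 (-2.79) and llmg_tRNA_19 (-2.58). tRNA took 31.4% and 34.3% of the coverage in the empty vector libraries and 15.6% and 18.2% in the overexpression libraries. The 6 copies of 5S rRNA, also short molecules, were lower as well, with a median of -1.49 and all 6 below both controls, while 23S rRNA features had a median of -0.01 and 16S features 1.54 with overlapping libraries. The rRNA list as a whole did not pass (adjusted p = 0.640), but passed as lower than other features with total base coverage scaling (adjusted p = 0.0452), where its median was 0.79; 5 of its 18 members fell adjusted over the list alone and 0 over all features. With the libraries scaled to total base coverage, the tRNA median was -0.96.

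**Figure D2:**
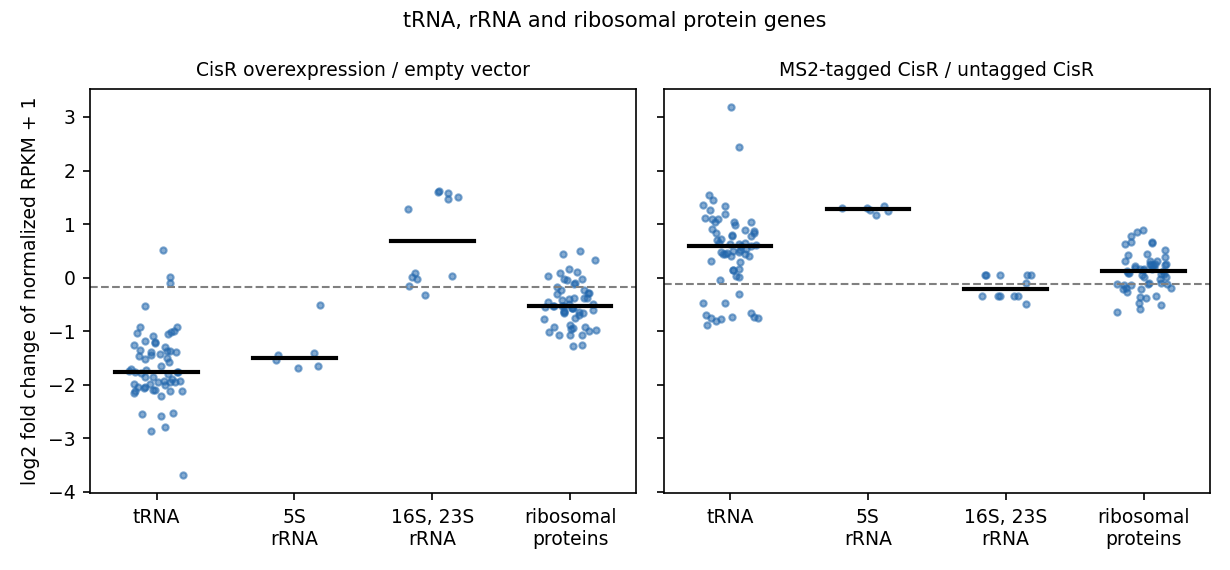
Log2 fold change of normalized RPKM + 1 for each tRNA, 5S rRNA, 16S and 23S rRNA and ribosomal protein feature in both comparisons, with a black bar at each group's median and a dashed line at the median of all features. The tRNA medians are -1.76 with overexpression and 0.58 with MS2-tagged CisR, and the 5S medians -1.49 and 1.28. With total base coverage scaling the ribosomal protein median with overexpression turns to 0.27, where the median of all features is 0.62.

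Of 56 ribosomal protein genes, 49 were lower with overexpression, with a median log2 fold change of -0.53. The adjusted p was 0.0189, and 0.947 with an estimated correlation. None passed over the list alone or over all features in limma, where the lowest adjusted p over the list alone was 0.182. The 4 with the largest differences were rpsR (-1.28), rpsG (-1.26), rplN (-1.08) and rpsK (-1.08). All 13 pyrimidine synthesis genes were lower (median -0.36, adjusted p = 0.0468, and adjusted p = 0.947 with an estimated correlation), 3 of them falling adjusted over the list alone and 0 over all features. The largest differences were in pyrG, CTP synthetase (-1.12), pyrR, the regulator of the pathway (-0.91), pyrP, the uracil permease (-0.82), and pyrH, uridylate kinase (-0.77, but 0.026 with total base coverage scaling). Of 15 glycolysis genes 14 were lower (median -0.55, adjusted p = 0.0468, and adjusted p = 0.947 with an estimated correlation), and 0 passed over the list alone or over all features. They included ldh, lactate dehydrogenase, at 59984.8 and 78606.5 normalized RPKM against 23668.6 and 42643.1 (-1.11), the pseudogene enoB (-1.12), glk (-0.89) and gapB (-0.84). Scaling to total base coverage turned the medians of these 3 lists to 0.27, 0.44 and 0.25. It moved the median of all features from -0.17 to 0.62, so the signs turned with that general shift. The 3 medians stayed below that of all features. With CisR, rRNA and tRNA left out of that total, the pyrimidine median was 0.12 and again none of the 3 passed. Relative to all features the 3 lists were then still lower, but none passed. The pyrimidine list also did not pass in camera with the replicate block (adjusted p = 0.0857) or with median-of-ratios scaling (0.0965, median -0.19). The ribosomal protein and glycolysis lists passed in both. Single libraries also decided these calls: the ribosomal protein list did not pass without empty vector replicate B (adjusted p = 0.0745) or overexpression replicate A (0.288). The pyrimidine list passed in none of the 4 fits without a library (0.0788 and 0.204 without empty vector replicates A and B, 0.129 and 0.145 without overexpression replicates A and B). The glycolysis list passed only without empty vector replicate A, with an adjusted p = 0.170 without replicate B and 0.266 and 0.0648 without overexpression replicates A and B.

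Transposases and insertion sequences passed in the upward direction (53 features, 30 higher, median 0.10, adjusted p = 0.0189, and adjusted p = 0.947 with an estimated correlation), with 0 past the threshold over the list alone or over all features. How reads from their copies were counted is not given, and the members named here had low values. Of these, llmg_0678 was listed at 0 in both empty vector libraries and at 51.8 and 17.5 with overexpression. The others named by the rule were llmg_0654 (-3.29) and the tnp981 copies llmg_1713 (2.79) and llmg_0549 (2.28), the last with overlapping libraries. With a mean base coverage of at least 1000, a limit chosen after seeing the data, the list's median was -0.20 and its adjusted p was 0.913. Without overexpression replicate A or B the adjusted p was 0.182 and 0.0714.

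The list of 6 cold shock protein genes did not pass (adjusted p = 0.878), with 3 members below and 1 above both empty vector libraries and a median of -0.14 that was 0.66 with total base coverage scaling, 0.34 with CisR, rRNA and tRNA left out of that total and 0.032 with median-of-ratios scaling. Of its members 0 passed over the list alone or over all features. cspC stood at 2755.7 and 2909.8 against 5729 and 3702.9 (0.70, adjusted p = 0.298), and cspD (-0.46), cspD2 (-0.35) and cspE (-0.19) were lower. The values of cspD, cspD2 and cspE turn positive with total base coverage scaling, which moved features by a median of 0.80. Among 16 chaperone and protease genes (adjusted p = 0.824) 0 passed over the list alone or over all features. The values were 0.51 for grpE, -0.43 for ftsH, -0.38 for htrA and -0.32 for dnaK, and the last 3 also turn positive with that scaling. Of the 148 other small RNAs tested, 89 were lower and 59 higher (median -0.30, adjusted p = 0.445), with 0 past the threshold over the list alone or over all features. With total base coverage scaling the median of this list turned to 0.46, and the list passed as lower than other features (adjusted p = 0.0202). LLMGnc_069 stood at 415.3 and 403.3 against 0 and 22.7, LLMGnc_186 at 156.7 and 139.1 against 0 and 49.5, LLMGnc_046 at 0 and 115.8 against 155.6 and 252.1, and LLMGnc_018 at 18.5 and 27.4 against 0 in both. Their mean base coverages were only 439.75, 217.25, 467 and 22.75. Overexpression replicate A, the library with the least coverage, had 299 features at 0, against 165 to 176 in the other libraries of the experiment.

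The second comparison asks which RNAs are held with MS2-tagged CisR. CisR had the highest log2 fold change of the features tested, at 6181.4 and 21360.1 normalized RPKM in the untagged libraries and 3312881.8 and 2728382.3 in the tagged libraries, 262-fold higher (log2 fold change 8.03, SE 0.64, n = 2 per group). It took 0.118% and 0.138% of the coverage in the tagged libraries. Next by p came ps357 (llmg_0852), a gene of unknown function annotated among the prophage-type ps loci, with 438.8 and 380.4 against 2456.4 and 2876.4, 6.49-fold (2.70, SE 0.31). pflA, the activating enzyme of pyruvate formate-lyase, had 929.3 and 1436.1 against 5247.9 and 4734.8 (2.11, SE 0.31). The small RNA LLMGnc_153 had 326.8 and 789.7 against 4395.8 and 4624.6 (3.15, SE 0.48), and busR, the repressor of osmolyte uptake, 1990.6 and 2986.1 against 9628.3 and 7848.3 (1.83, SE 0.30).

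None of these passed in the 4 libraries of the comparison. limma found 0 features higher and 0 lower among 2659 at a false discovery rate of 0.05, and 156 at an unadjusted p under 0.05, 79 higher and 77 lower, where 133 would be reached by chance. With total base coverage scaling 63 were higher and 39 lower, with CisR, rRNA and tRNA left out of that total 142 and 27, and with median-of-ratios scaling 107 and 55. The adjusted p was 0.0972 for CisR, 0.341 for ps357, 0.597 for pflA, LLMGnc_153 and busR, and ranged for CisR from 1.3e-40, with total base coverage scaling, to 0.401, without untagged replicate A. Fitting all 8 libraries together, planned before the data were examined, called 5 features: CisR, ps357, pflA and LLMGnc_153 as higher and LLMGnc_023 as lower. That fit takes 1 spread per feature from both experiments, which were scaled separately. Replicates correlated more closely in the overexpression experiment (r = 0.970 and 0.931) than in the MAPS experiment (0.917 and 0.905). These calls thus rest partly on the spread of the other experiment, and LLMGnc_023 had a mean base coverage of 52. With a mean base coverage of at least 1000, chosen after seeing the data, 3 were higher: CisR, ps357 and LLMGnc_153. The last, at a mean of 1380.5, reached that minimum mainly through its tagged libraries, so its change helped it to be included. The groups did not overlap for 38.4% of features, where chance gives 33.3%.

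**Figure D3:**
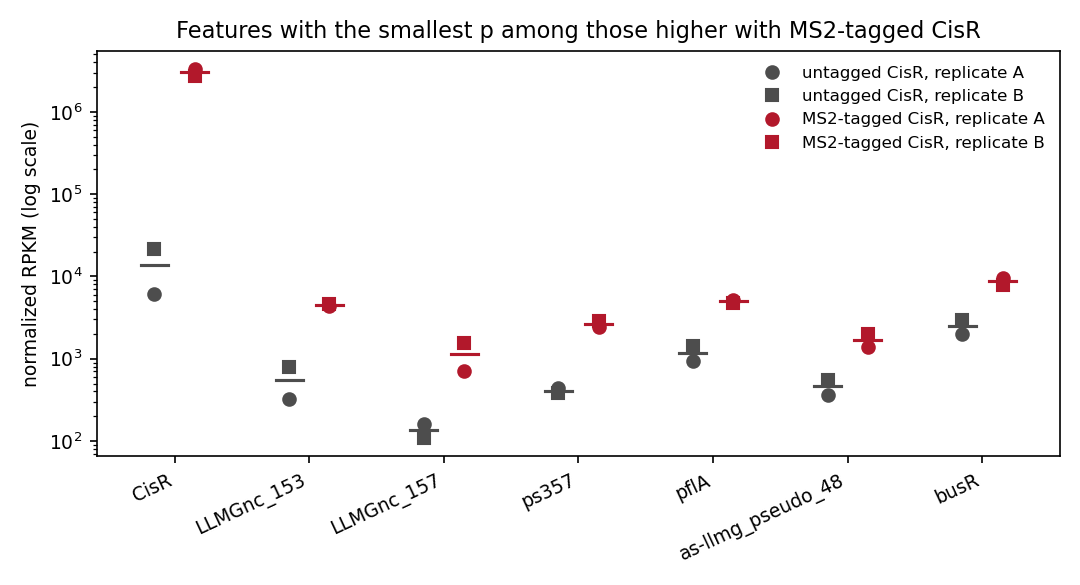
Normalized RPKM on a log scale for CisR and the 6 other features with the smallest p among those higher with MS2-tagged CisR, except LLMGnc_006, which is listed at 0 in 1 library. Grey marks are untagged and red marks tagged libraries, circles replicate A and squares replicate B, with a bar at each mean; for ps357 the values are 438.8 and 380.4 against 2456.4 and 2876.4.

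ps357 lies on the plus strand at 819287 to 820246, pflA on the minus strand at 1986117 to 1986908, busR on the plus strand at 1010159 to 1010779, and LLMGnc_153 on the minus strand at 2063763 to 2063863. The other features higher by the same rule were LLMGnc_157 at 2064112 to 2064212 (161 and 108.8 against 707.6 and 1565.3), the antisense RNA as-llmg_pseudo_48 (1.90) and LLMGnc_006 (0 and 34.8 against 918.9 and 1841.8), each at an adjusted p = 0.749. On the lower side, 5 of the 8 features with the smallest p were listed at 0 in both tagged libraries: as-ps614 (160 and 426.4 without the tag), LLMGnc_146 (129.2 and 169.7), LLMGnc_023 (108.9 and 206.7), llmg_1389 (136.5 and 76) and LLMGnc_158 (109.9 and 84.8). ps307 stood at 103.1 and 164.6 against 3 and 0. Only groES, the co-chaperonin (-1.18), and llmg_1523 (-1.30) had higher levels, with 14175.2 and 10055.4 against 5647 and 4900.9 for groES. Windows such as LLMGnc_152 and LLMGnc_153 overlap on opposite strands, and whether counting used the strand is not given in the sources used here. In the MAPS libraries the antisense windows inside single genes had a median density of 0 to 0.0244 of the gene's own. Counting without strand would give about the gene's own density.

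tRNA features were higher with the tag, 50 of 63, with a median log2 fold change of 0.58 (adjusted p = 3.5e-04, and adjusted p = 0.990 with an estimated correlation), and 0 passed over the list alone or over all features. The call was lost without untagged replicate A (adjusted p = 0.512) or tagged replicate B (0.273). The largest values were in llmg_tRNA_33 (3.18), llmg_tRNA_15 (2.44), llmg_tRNA_35 (1.54) and llmg_tRNA_37 (1.44). The rRNA list passed (18 features, median 0.05, adjusted p = 0.0281, and adjusted p = 0.990 with an estimated correlation), with 0 past the threshold over the list alone or over all features. Its 6 copies of 5S rRNA lay above both untagged libraries with a median of 1.28, among them llmg_rRNA_48b (1.34), llmg_rRNA_6a (1.31), llmg_2466a (1.30) and llmg_2426a (1.27). The medians of 16S and 23S rRNA were -0.35 and 0.05. Without untagged replicate A the rRNA list's adjusted p was 0.689 and its median -0.63, and without tagged replicate A they were 0.175 and -0.05.

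Of 13 pyrimidine synthesis genes, 12 were lower with the tag, 11 of them below both untagged libraries (median -0.59, adjusted p = 0.00612, and adjusted p = 0.990 with an estimated correlation). None passed over the list alone or over all features. carB (-0.79), pyrC (-0.75), pyrP (-0.72) and pyrDA (-0.69), all enzymes or transporters of the pathway, had the largest differences. Without untagged replicate A the adjusted p was 0.0980, and without tagged replicate B it was 0.159. Of 17 genes of tryptophan and other aromatic amino acid synthesis, 16 were lower (median -0.42, adjusted p = 0.0281, and adjusted p = 0.990 with an estimated correlation), with 0 past the threshold over the list alone or over all features. Only 6 lay below both untagged libraries, and of all protein-coding genes tested 1434 of 2327 were lower. The largest differences were in trpC (-1.74), trpF (-1.08), trpG (-0.93) and trpB (-0.86), with overlapping libraries for trpF and trpG. That call was lost without untagged replicate A (adjusted p = 0.214) or tagged replicate B (0.335). With the libraries scaled to total base coverage, only the tRNA list of these 4 passed (adjusted p = 0.0102), and the other 3 had an adjusted p of 0.752.

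Cold shock protein genes had 0 of 6 members past the threshold over the list alone or over all features (adjusted p = 0.981), with cspA at 0.94, cspE at -0.39, cspC at -0.22 and cspB at -0.17, of which cspB turns positive with total base coverage scaling and cspB and cspC when CisR, rRNA and tRNA are left out of that total. Of 16 chaperone and protease genes 15 were lower (adjusted p = 0.136), and 0 passed over the list alone or over all features. They included groES (-1.18), ctsR, the regulator of the clp genes (-0.73), clpB (-0.39) and htrA (-0.36). Of 143 other small RNAs 87 were higher (median 0.42, adjusted p = 0.0517, and adjusted p = 0.990 with an estimated correlation). Again 0 passed the threshold over the list alone or over all features. This list passed with a pseudocount of 10 (adjusted p = 0.0146), all 8 libraries (0.0199) or a mean base coverage of at least 1000 (0.00193). It also passed without untagged replicate A (0.0280), untagged replicate B (1.6e-04) or tagged replicate A (8.9e-04), while its adjusted p was 0.754 with total base coverage scaling. In 2 further lists 1 gene rose adjusted over the list alone and 0 over all features: pflA among 15 fermentation genes and busR among 14 glutamine and osmolyte transport genes.

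The last comparison asks whether the RNAs enriched with the tag are those whose level differs with overexpression. Over 2566 features tested in both, with CisR left out, 0 were enriched and 0 changed in limma, so 0 were shared; 145 and 399 of these features had an unadjusted p under 0.05 in the MAPS and overexpression comparisons. Across features, log2 fold changes of the comparisons had r = 0.0031 and a Spearman rho of -0.02 over 2567 features, which are not independent replicates. ps357, pflA, busR and LLMGnc_153 had overexpression log2 fold changes of 0.14, -0.49, 0.28 and -0.19, none past the threshold. The 50 most enriched and the 50 most changed features shared 11, where 0.974 would be shared by chance (Fisher's exact test, two-sided, p = 1.0e-09, which treats features as independent). Of these, 3 were higher with overexpression and 8 lower. The 10 with the highest values with the tag were LLMGnc_078 (4.81), ps130 (4.80), ps428 (4.49), as-llmg_0626 (4.48), as-llmg_1727 (4.47), ps514 (4.41), LLMGnc_069 (4.19), llmg_2402 (3.63), ps336 (3.57) and llmg_0087 (3.01). All 11 had a mean base coverage under 128 in the MAPS libraries.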

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

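The overexpression of CisR kept its direction and its call under all alternatives run, with log2 fold changes of 5.43 to 6.50. With MS2-tagged CisR, the CisR value stayed between 7.14 and 8.93, and the call passed at 8.24 with total base coverage scaling, at 8.30 with CisR, rRNA and tRNA left out of that total, and at 8.03 both with all 8 libraries in 1 fit and with a mean base coverage of at least 1000. The last setting, median-of-ratios scaling, the fit without tRNA and rRNA, the crossed pairing and the list tests under other scalings and filters were chosen after seeing the data. The cause of the differences below was not tested. Read-count tests and their scalings, planned for the case of read counts, were not run because the values were treated as base coverage. The unknown number of reads and 2 libraries per group limit what could be detected.

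Features past the threshold with overexpression numbered 28 to 605 when a library was left out, where the lone library of a group is assumed to vary like the other group, and 1 under the other settings except the replicate block. The replicate block gave 101, 45 of them tRNA features. Over all features the same-letter deviations correlated at -0.02 in the overexpression and -0.11 in the MAPS comparison, so the main fits did not pair the letters. This does not exclude a pairing for tRNA, whose median was higher in B than in A in every group. With the empty vector it was 696663.5 in A and 875738.5 in B, and with overexpression 181422.4 and 301645.4. A crossed pairing was not run for overexpression. In the MAPS comparison the crossed pairing called 0, as did the block. There the count was 1 at a false discovery rate of 0.1, 5 with total base coverage scaling, 1 with CisR, rRNA and tRNA left out of that total, 5 with all 8 libraries and 3 with the coverage minimum, and 0 when any library was left out. The 5 with total base coverage scaling were CisR, llmg_1397, llmg_tRNA_33 and LLMGnc_006 as higher and as-ps614 as lower; limma's prior degrees of freedom were infinite there and in both overexpression fits without an empty vector library, so 1 spread was assumed for all features of a level.

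With overexpression 5 lists passed, against 0 with an estimated correlation, 0 with fry, 2 with the reduced total and 7 with total base coverage scaling. In each of those scalings 1 of the 5, the tRNA list, was among them. The number was 1 to 7 without a library, with 1 to 4 of the 5 among them. In the MAPS comparison 4 lists passed, against 0 with an estimated correlation and 0 with fry. With 2 libraries per group hardly any list could pass in these 2 tests. The MAPS number was 1 with total base coverage scaling, 1 with the reduced total, 8 with the coverage minimum and 1 to 9 without a library. With CisR left out, at least 1 of the lists compared was empty under each alternative of the overlap that used a threshold, so its value of 0 there says nothing about shared features. The 50 most enriched and the 50 most changed in either direction shared 11. The correlation across features was -0.0035 with total base coverage scaling and -0.0042 with the coverage minimum.

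Named features that turned sign had not passed the threshold. With overexpression, total base coverage scaling moved features by a median of 0.80 and the reduced total by 0.48. In the MAPS comparison these shifts were 0.21 and 0.26. Values slightly below 0 turn positive through such a shift, whether or not they differ from other features. With overexpression and total base coverage scaling the log2 fold changes were 0.026 for pyrH, 0.34 for cspD, 0.45 for cspD2, 0.61 for cspE, 0.37 for ftsH, 0.42 for htrA and 0.48 for dnaK. With the reduced total they were 0.020 for cspD, 0.13 for cspD2, 0.29 for cspE, 0.046 for ftsH, 0.10 for htrA and 0.16 for dnaK. Without a library, tnp981 at llmg_0549 ranged from -0.042 to 4.60 and dnaK from -0.84 to 0.21. In the MAPS comparison cspB was 0.034 with total base coverage scaling and 0.093 with the reduced total, where cspC was 0.041. Without a library, trpG ranged from -1.94 to 0.084, cspA from -0.075 to 1.96, cspE from -0.98 to 0.19 and cspC from -1.04 to 0.60.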

Other observations

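The tests of the tRNA pattern below were chosen after the result was seen, and the readings of the test of levels with overexpression and of the test of the 11 shared features were changed after their results were seen; the other tests were set before their results. The features in this and the next paragraph were also chosen after their values were seen. With CisR overexpression, 32 of 38 antisense RNA features were lower, with a median log2 fold change of -0.95, and 19 lay below both empty vector libraries. Most features were lower in this comparison, 1439 of 2293 among protein-coding genes. With total base coverage scaling 22 were lower (median -0.16), and with CisR, rRNA and tRNA left out of that total 26 were (median -0.48). Of these features 0 passed in limma, and 9 had an unadjusted p under 0.05. In the overexpression experiment, antisense windows inside a single gene had a median density of 0 to 0.0485 of the gene's own per library, where counting without strand would give about the gene's own density. All 14 genes of the RNase, helicase and RNA polymerase list (median -0.36, adjusted p = 0.0931) and 13 of 14 translation factor genes (median -0.48, adjusted p = 0.0838) were lower, but the lists did not pass. Their medians turned to 0.44 and 0.32 with total base coverage scaling, where the median of all features was 0.62. Adjusted over the list alone, copR, a regulator gene of the metal list (-1.18), and argR, the arginine repressor gene (-0.76), fell, and pepN rose (1.51), while 0 of these 3 passed over all features. With total base coverage scaling the argR value turned to 0.045 and the copR value was -0.38.

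In the MAPS libraries, ps358, which begins at 820437 after ps357 on the same strand, stood at 776.4 and 1227.6 against 1975 and 3210.9 (log2 fold change 1.37, adjusted p = 0.749 in limma). LLMGnc_062, which lies between them, was at -0.32, with a mean base coverage of only 57.25, and ps356, before ps357, at 0.39. LLMGnc_063, after ps358 on that strand, was at 1.27 here (SE 0.88), with overlapping libraries at 565.8 and 1244.4 against 856.4 and 4782.9. With overexpression LLMGnc_063 was at 1.33, while ps358 was at -1.07. In the small RNA cluster between 2063524 and 2064335 the windows differed: LLMGnc_153 and LLMGnc_157 on the minus strand were at 3.15 and 2.98, while LLMGnc_155, between them on that strand, stood at 155.2 and 332.9 against 65.6 and 0. LLMGnc_158, the next on that strand, was listed at 0 in both tagged libraries. LLMGnc_155 and LLMGnc_158 had mean base coverages of 88.75 and 38.25, so the contrast between the windows rests on values near the floor. Among features with a mean base coverage of at least 1000 in both experiments, the top 50 of each shared 8, and all 8 were lower with overexpression; that they were higher with the tag follows from the choice. They were LLMGnc_064, 5 tRNA features, the 5S rRNA copy llmg_2466a and fruR, annotated as a lactose transport regulator, whose empty vector libraries stood far apart at 753.9 and 9508. The tRNA and 5S features have copies that may share reads, so these 8 cannot be taken as independent.

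The first pattern weighed is the lower tRNA level with CisR overexpression. The authors' median scaling does not account for it alone: with total base coverage scaling the tRNA median was still -0.96, and each of the 4 pairs of libraries gave a lower value, from -0.65 to -1.23. Coverage taken up by CisR is too small, at 0.880% of the share that tRNA lost. A lower yield of short RNA molecules in the overexpression libraries may account for it. The 5S rRNA median was -1.49, while 16S and 23S features together had a median of 0.69. That value lies between 16S features at 1.54, with overlapping libraries, and 23S features at -0.01. The 149 small RNA features, CisR among them, did not fall alike: their median was -0.26, with 30 below and 33 above both controls. The lengths of these RNAs are not given, so the yield of short molecules stays open. An effect of CisR on tRNA and 5S rRNA levels stays open as well and was not tested.

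The second pattern is the set of features most enriched with MS2-tagged CisR. Whether they change in level with overexpression stays open: the 50 highest had a median of -0.35 there, at percentile 36.8 of 10000 lists matched on level, which a bound set beforehand took as evidence against it, but 21 were higher and 29 lower, so the median decides nothing. Purification of whole transcripts stays open. Among the 50 most enriched genes were 3 same-strand adjacent pairs, a number that 4.32% of random lists reached, against 2 among the 50 most depleted. No gene of the 3 pairs had a mean base coverage above 301. These random lists were not matched on level or coverage, so the number of pairs cannot tell purification from low coverage of neighbouring genes. Few reads behind the features stay open for most of the set, since 2 of the 50 had a mean base coverage of at least 1000 and the median was 71.5. Binding to CisR stays open and was not tested.

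The third pattern is the 11 features shared by the 50 most enriched and the 50 most changed, which may come from low coverage that gives the same features large chance changes in both experiments. Their median of mean base coverage was 40.2 in the MAPS libraries, and 0 of them had at least 1000 in both experiments. Among the 1857 features that did, the top 50 of each shared 8, where 1.35 would be shared by chance if features were independent. A bound set before this result took 5 or more as evidence against low coverage, and it was met; it was set aside afterwards because the 8 are all other features than the 11. Low coverage and binding cannot be told apart for the 11, which are too thinly covered to decide.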
